A study of Homo sapiens with 5 samples.

How the data were processed

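Poly(A) RNA was sequenced from HEK293T cells in 2 groups, 3 libraries of untreated cells and 2 libraries of cells given ascorbic acid. Per the labels' protocols, cells were seeded for 24 h, treated for a further 24 or 36 h with the medium changed every 6 h, lysed in Trizol, and mRNA was taken on capture beads before library preparation. The deposited table holds counts of reads per gene, as whole numbers, for 28278 gene symbols and 5 libraries. Per the submitters' processing notes, Trimmomatic 0.39, STAR, featureCounts and DESeq2 were used with the hg38 (GRCh38) build. The annotation, the strand setting and the treatment of overlapping or multiply mapped reads are not given in the sources used here, so the counts of overlapping genes, antisense pairs and close paralogs are uncertain. The table's columns were assigned to samples by name, with the prefix "con" read as control and "vc" as vitamin C. Total counts per library were 57212071, 38229722 and 35106664 in control replicates 1 to 3 and 48015766 and 41739602 in treated replicates 1 and 2. In each library, 71.3 to 75.9% of counts from 1 to 10 were even, so pairs appear to have been counted by their ends and counting error is larger than the counts imply.

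No row lacked a gene name. Gene positions, transcript length, GC content and exon overlaps were taken from GENCODE release 29 on GRCh38, to which 26218 of 28278 symbols matched. These were used for positions and for the GC and length check, which covered 97% of tested genes and 99.4% of called genes.

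Genes were filtered with filterByExpr by group and scaled with TMM factors (0.984 to 1.03), and the groups were compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit with a robust prior, glmQLFTest, two-sided) over the 5 libraries without covariates. Adjusted p-values are Benjamini-Hochberg values over 15271 genes, with a threshold of 0.05. CPM values use TMM-scaled totals. Standard errors of log2 fold changes were derived from the fold change and the F statistic. The biological coefficient of variation was 4.6%. Replicates of a group differed by more than counting noise, with chi-square per degree of freedom of 3.81 to 6.85, and were kept as separate libraries. Counts were simulated for this comparison (15138 genes, 50 changed at each fold). The test recovered 62% of changed genes at a fold of 1.2, 98% at 1.5 and 100% at 2 and 3. Of 189 calls 9 were false. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery of lower genes was not measured.

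Before the data were examined, 43 gene lists with 1253 genes were fixed. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 40 lists with at least 5 tested members. With a preset correlation 20 lists passed, and with an estimated correlation 0 did (lowest adjusted p = 0.218, 7 lists under an unadjusted 0.05), while fry called 18, of which 14 are among the 20. Camera compares a list with the other genes and fry tests it against no change, so they answer different questions. On simulated data with independent genes, both forms of camera called 20 of 20 raised lists and 0 of 20 unchanged lists. Genes of a real list can be correlated, so this does not measure false calls that come from correlation. The genes named were also fixed by rule. They are the 10 largest increases and 10 largest decreases past the threshold with a mean of at least 5 CPM and groups that do not overlap (clone and small nucleolar or nuclear RNA symbols were skipped), up to 3 called members of each list by smallest p or else its 2 highest expressed members, and a panel of 20 genes. Genes outside the rule were chosen after their values were seen: SLC40A1, COL1A1, COL4A2, LAMC1 and TRAPPC9 in the results, the fibroblast markers too low to test (COL1A2, LUM, DCN, THY1, POSTN and FAP), and those of the last part. The values of 3 genes that the rule selects are not reported here.

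The alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals, upper-quartile factors, no filter, a filter of 5 CPM in 2 libraries, the replicate number as a block, no robust prior, a test against a fold of 1.2 (glmTreat), each library left out, and for lists fry and an estimated correlation. Those chosen after seeing the data were a cyclic loess fit that removes the trend with expression, thinning to the shallowest library, halved counts, and removal of GC and length trends by mgcv 1.9.3, first without and then with centring of each library's correction. The cyclic loess fit also tests log CPM with limma in place of the edgeR count model. A call that ended there is therefore not shown to have ended through the trend. With 1 treated library left out, the other is assumed to vary like the controls. The planned share of counts from mitochondrially encoded genes was not computed, since 0 of the 13 genes on that list were in the table used here. The test for background reads was first run with classes cut on all 5 libraries, which limits what a class can gain, and then with classes cut on a control left out of the comparison. The code of the S phase test was corrected to follow its written rule after its first outcome, undecided, had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.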

Results

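RNA was sequenced from HEK293T cells, an established human embryonic kidney line, that were either left untreated or given ascorbic acid (vitamin C). Ascorbic acid keeps iron in its ferrous form and so serves the Fe(II) and 2-oxoglutarate dependent dioxygenases, the enzyme family to which the TET DNA hydroxylases, the JmjC histone demethylases, the RNA demethylases FTO and ALKBH5 and the collagen hydroxylases belong. Messenger RNA was captured on beads, and the count table held 3 control libraries and 2 ascorbic acid libraries. The control libraries held 57212071, 38229722 and 35106664 gene counts, and the treated libraries 48015766 and 41739602. Most low counts were even (71.3 to 75.9% of the counts from 1 to 10 in each library), as when both ends of a read pair are counted. The number of sequenced fragments behind a value may therefore be below its count. The dose is not given in the labels, which give a treatment of 24 h for a DNA methylation test and 36 h for an RNA methylation test without saying which applied to these libraries. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

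Which genes differ in level after ascorbic acid was asked by comparing the 2 treated libraries with the 3 controls. The 10 largest increases were taken among called genes with a mean of at least 5 CPM and groups that do not overlap. KRT8, an intermediate filament keratin (chromosome 12, 52897187 to 52949954, GRCh38), rose 2.77-fold, from 4.41 ± 0.298 CPM (SD, n = 3) to 12.3 ± 0.227 CPM (SD, n = 2). The collagen genes COL3A1 (chromosome 2, 188974320 to 189012746) and COL5A2 (chromosome 2, 189031896 to 189225312) rose 2.43-fold and 2.21-fold. On the log2 scale (± SE), S100A11, a calcium-binding protein, rose by 1.07 ± 0.07, CCN2, a matricellular growth factor, by 1.07 ± 0.13, and HSPB1, a small heat shock protein, by 1.03 ± 0.08. The class II antigen-presentation gene HLA-DPA1 (1.03 ± 0.11), the inositol phosphatase gene INPP5D (1.03 ± 0.11), the annexin ANXA1 (1.01 ± 0.11) and NYNRIN (0.97 ± 0.10) completed the 10 largest increases, with edgeR adjusted p from 3.34e-12 for S100A11 to 1.3e-06 for CCN2. None of these 10 calls was lost in any alternative fit. KRT8 and HLA-DPA1 have close paralogs or pseudogenes, so their counts are uncertain where reads match more than one copy.

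**Figure D1:**
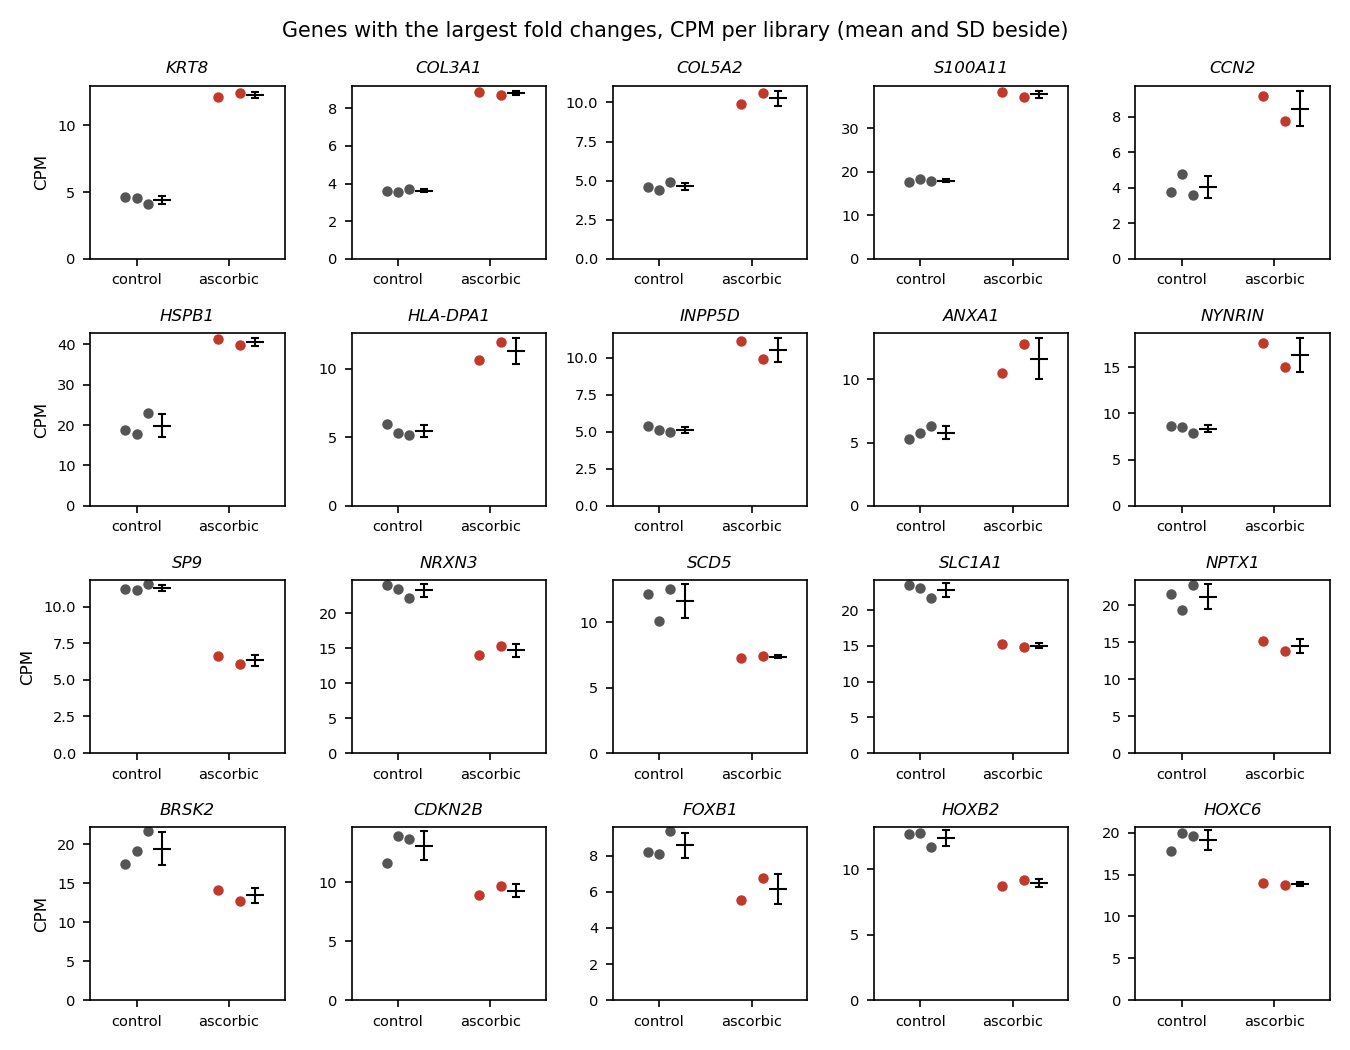
CPM per library for the 20 genes with the largest increases (upper rows) and decreases (lower rows), with control libraries in grey, ascorbic acid libraries in red, and the mean and SD of each group beside the points. The genes were chosen among those whose groups do not overlap.

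The 10 largest decreases under the same rule were smaller. SP9, a zinc finger transcription factor of developing forebrain and limb (chromosome 2, 174334946 to 174338492), fell from 11.3 ± 0.199 CPM (SD, n = 3) to 6.33 ± 0.382 CPM (SD, n = 2), a log2 fold change of -0.83 ± 0.11 (edgeR adjusted p = 2.08e-06). The synaptic adhesion gene NRXN3 (-0.67 ± 0.08), the desaturase gene SCD5 (-0.66 ± 0.11), the glutamate transporter gene SLC1A1 (-0.60 ± 0.08), the pentraxin NPTX1 (-0.55 ± 0.09) and the kinase gene BRSK2 (-0.52 ± 0.09) followed. CDKN2B, a cyclin-dependent kinase inhibitor (-0.49 ± 0.10), FOXB1 (-0.48 ± 0.12), HOXB2 (-0.47 ± 0.10) and HOXC6 (-0.46 ± 0.08) completed the 10, with adjusted p from 9.57e-07 for NRXN3 to 0.00658 for FOXB1. One of these calls depended on a single library. The FOXB1 call ended without treated 1 (-0.34, adjusted p = 0.139). CDKN2B, FOXB1, HOXB2 and HOXC6 were also not called when tested against a fold of 1.2.

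Of 15271 genes tested, 2182 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1303 higher and 879 lower with ascorbic acid. Most changes were small, with a median fold of 1.36 among the higher genes and 0.871 among the lower genes. At least 1.5-fold higher were 483 genes and at least that much lower were 18. At a fold of 2 these counts were 181 and 9. The higher genes were expressed at a median of 10.3 CPM and the lower genes at 81.5 CPM. The median log2 fold change was 0.21 in the 2402 tested genes below 1 CPM and -0.07 in the 913 genes at or above 200 CPM. The groups did not overlap in 43.1% of tested genes, where chance gives 20%. Scaling by library totals alone gave 1712 higher and 389 lower genes, and an added removal of GC and length trends that also moved the centre of each library gave 1152 higher and 3464 lower, so the split by direction depends on the centring. Without control replicate 1 the call count was 1180, with 335 lower genes, and against a fold of 1.2 it was 286.

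**Figure D2:**
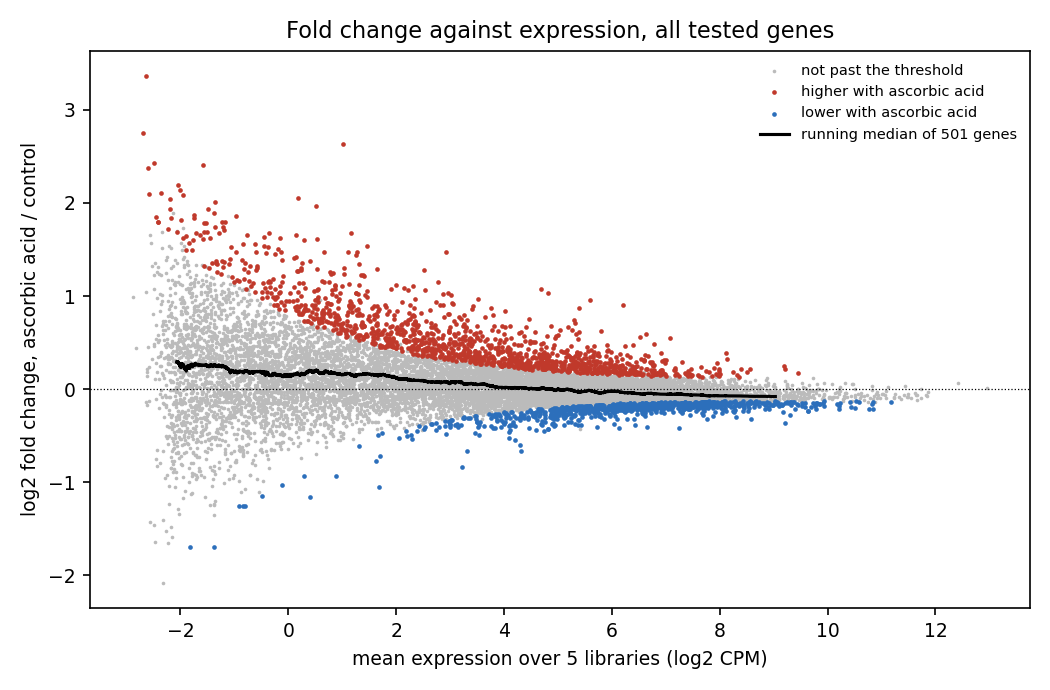
Log2 fold change of each tested gene against its mean expression in log2 CPM over the 5 libraries, with genes past the adjusted p of 0.05 in red (1303 higher) and blue (879 lower) and the running median as a black line. The line lies above 0 at low expression and below 0 at high expression.

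FBXL5, the iron-sensing subunit of the ubiquitin ligase that removes iron regulatory proteins, had the smallest p of all tested genes. It went from 54.8 ± 1.47 CPM (SD, n = 3) to 102 ± 1.56 CPM (SD, n = 2), a log2 fold change of 0.90 ± 0.05 (edgeR adjusted p = 5.35e-13). HMOX1, which breaks down heme, rose by 0.88 ± 0.06 (1.73e-11), and the quinone reductase gene NQO1 by 0.87 ± 0.09 (4.62e-08). The mitochondrial iron importer gene SLC25A28 rose by 0.57 ± 0.07, the ferritin light chain FTL by 0.39 ± 0.05 and the ferritin heavy chain FTH1 by 0.31 ± 0.05. Of 28 tested iron homeostasis genes 9 rose, 3 fell and 16 did not pass, with 10 higher and 4 lower adjusted over the list alone. As a list, iron homeostasis genes had camera adjusted p = 0.00213, and adjusted p = 0.218 with an estimated correlation. The iron exporter gene SLC40A1 was among those that rose (0.71), and ACO1, an iron regulatory protein gene, among those that fell (-0.23). TFRC, the transferrin receptor gene, had 0.06 ± 0.04 and did not pass. Of 26 NRF2 targets 6 rose, 0 fell and 20 did not pass, with 7 higher and 0 lower adjusted over the list alone. As a list, NRF2 targets had camera adjusted p = 8.86e-05, and adjusted p = 0.294 with an estimated correlation. FTL and FTH1 are members of both lists. SLC7A11, the cystine transporter gene, rose by 0.20 ± 0.06. The SLC7A11 call ended without treated 2, control 1 or control 3 (0.14 to 0.20, adjusted p = 0.0693 to 0.201). FTH1 shares 62.4% of its exon length with BEST1 on the opposite strand and, like FTL, has pseudogenes, so its value is uncertain.

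MT1X (0.69 ± 0.11) and MT2A (0.60 ± 0.12), small metal-binding proteins with near-identical copies, rose. Of 7 tested metal response genes 2 rose, 0 fell and 5 did not pass, with 2 higher and 0 lower adjusted over the list alone. As a list, metal response genes had camera adjusted p = 0.0349, and adjusted p = 0.310 with an estimated correlation. That call ended without control replicate 3 (adjusted p = 0.0772), without treated replicate 2 (0.153) and with the trend over expression removed (0.061). Among 27 antioxidant enzymes 4 rose, 3 fell and 20 did not pass, with 4 higher and 3 lower adjusted over the list alone. The peroxiredoxin PRDX4 had -0.32 ± 0.05, and the glutathione peroxidases GPX3 and GPX4 had 0.41 ± 0.08 and -0.20 ± 0.05. The antioxidant list did not pass (camera adjusted p = 0.218), its median and mean differ in sign, and it passed without treated replicate 1 (adjusted p = 0.0185). The GPX4 call ended without treated 2 (-0.14, adjusted p = 0.0778).

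Of 34 collagen and matrix genes 16 rose, 2 fell and 16 did not pass, with 20 higher and 2 lower adjusted over the list alone. As a list, matrix genes had camera adjusted p = 2.15e-13, and adjusted p = 0.218 with an estimated correlation. SPARC, a collagen-binding matrix glycoprotein, rose by 0.71 ± 0.06 from 31.7 ± 0.801 CPM (SD, n = 3) to 51.9 ± 3.40 CPM (SD, n = 2) (edgeR adjusted p = 4.09e-09). COL3A1 rose by 1.28 ± 0.12, COL5A2 by 1.15 ± 0.11 and COL1A1 by 0.67, while the basement membrane genes COL4A2 (-0.17) and LAMC1 (-0.14) fell. Of 11 fibroblast markers tested 4 rose, 0 fell and 7 did not pass, with 6 higher and 0 lower adjusted over the list alone. As a list, fibroblast markers had camera adjusted p = 4.29e-07, and adjusted p = 0.218 with an estimated correlation. The markers that rose were COL3A1 and COL1A1, which are also matrix list members, the gelatinase MMP2 (1.09 ± 0.14) and the smooth muscle actin ACTA2 (0.68 ± 0.11). Of the fibroblast transcripts too low to test, COL1A2, DCN, THY1 and FAP had 0 to 2 counts in every library. LUM had 8, 6 and 4 counts in the controls and 7 and 11 in the treated libraries, and POSTN had 12, 2 and 1 against 6 and 14.

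Of 8 keratinocyte and epithelial markers tested 3 rose, 0 fell and 5 did not pass, with 4 higher and 1 lower adjusted over the list alone. The 3 that rose were EPCAM (1.80 ± 0.42), KRT17 (1.80 ± 0.61) and SFN (1.17 ± 0.40), each below 1 CPM in both groups. At such levels DESeq2 may give no adjusted p, and a call is then also listed as ended with DESeq2. The keratinocyte list did not pass (camera adjusted p = 0.0823), and passed without control replicate 2 (adjusted p = 0.0427), and fry, which tests against no change, called it (0.027). The EPCAM call ended without treated 2 (1.66, adjusted p = 0.0573) and with DESeq2 (1.80). The KRT17 call ended without treated 1, treated 2, control 1, control 2 or control 3 (1.61 to 1.98, adjusted p = 0.0685 to 0.246) and with DESeq2, no filter or the trend removed (1.17 to 1.85). The SFN call ended without treated 2, control 1 or control 2 (0.63 to 1.12, adjusted p = 0.0827 to 0.529) and with DESeq2, limma-voom, the trend removed or thinning (0.76 to 1.17). Of 7 proximal tubule markers 1 rose, 1 fell and 5 did not pass, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.596). The endocytic receptor gene LRP2 fell, with -0.45 ± 0.07, and SLC13A3 rose by 0.99 ± 0.17. Only 4 haematopoietic markers were tested, of which LCP1 rose by 0.17 ± 0.05, with 2 higher adjusted over the list alone. The LCP1 call ended without treated 1, control 2 or control 3 (0.10 to 0.17, adjusted p = 0.0768 to 0.345) and with DESeq2 (0.17). The 1 hepatocyte marker tested, TF, had 1.02 ± 0.62 and did not pass. Of 10 neural markers that HEK293 cells express 4 rose, 0 fell and 6 did not pass, with 5 higher and 0 lower adjusted over the list alone. As a list, neural markers had camera adjusted p = 0.00158, and adjusted p = 0.338 with an estimated correlation. The neurofilament gene NEFM rose by 0.75 ± 0.07, NES by 0.72 ± 0.14 and MAP2 by 0.85 ± 0.28. The MAP2 call ended without treated 1 or control 1 (0.61 to 0.63, adjusted p = 0.196 to 0.342) and with DESeq2, the trend removed or thinning (0.59 to 0.83).

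**Figure D3:**
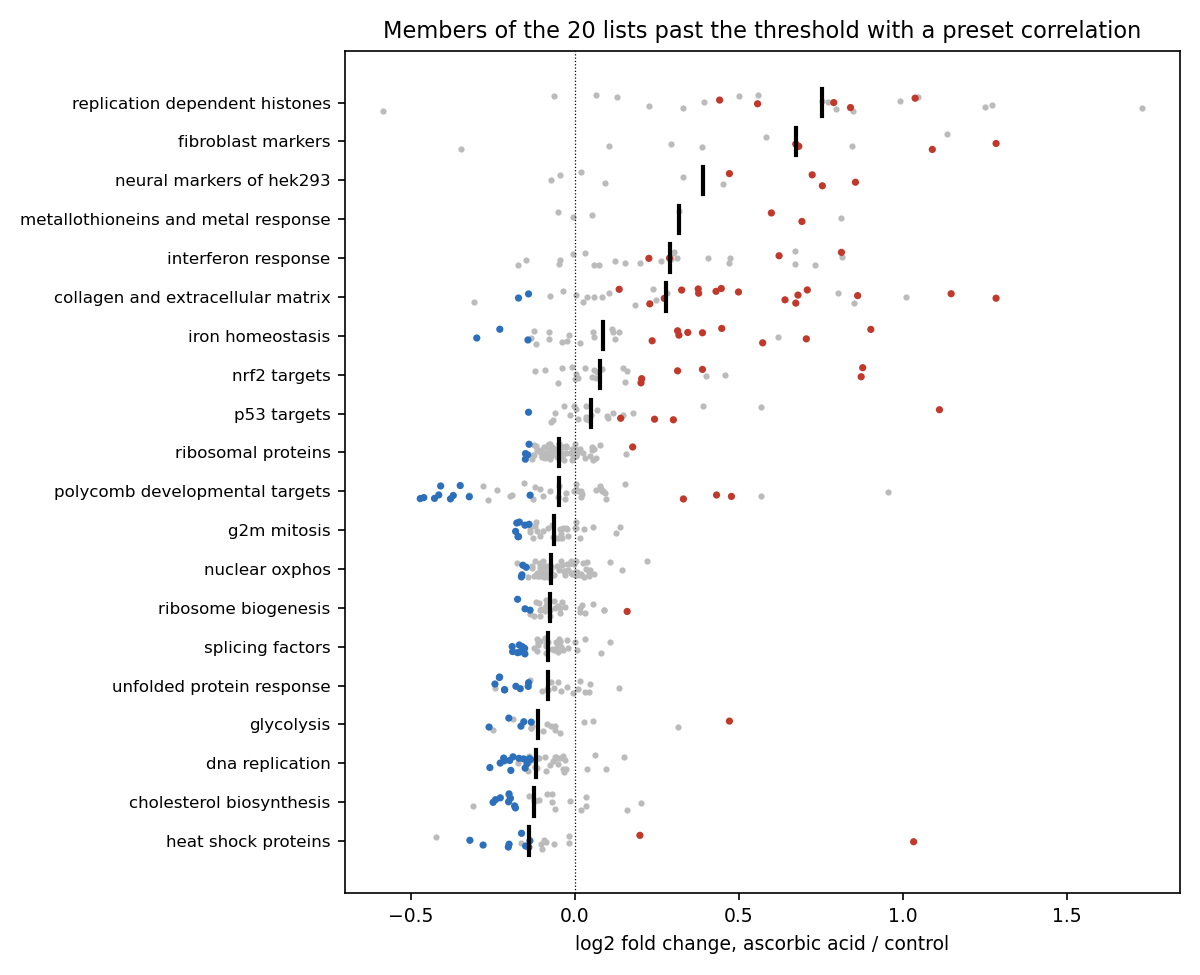
Log2 fold change of every tested member of the 20 gene lists past the threshold with a preset correlation, with members called higher in red, called lower in blue and others in grey, and the list median as a black bar. Medians of the matrix, histone and fibroblast lists lie to the right of 0, and those of the DNA replication and heat shock lists to the left.

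TET1 (0.05 ± 0.06), TET2 (-0.15 ± 0.07) and TET3 (0.00 ± 0.06), which oxidise 5-methylcytosine, did not pass. Their edgeR adjusted p ran from 0.121 for TET2 to 0.984 for TET3, and TET2 passed without treated replicate 2 (-0.27, adjusted p = 0.0173) and in both added fits with GC and length trends removed (-0.22 uncentred, -0.15 centred). FTO, the RNA demethylase gene, rose by 0.31 ± 0.05 (5.48e-05), from 88.5 ± 0.438 CPM (SD, n = 3) to 109.7 ± 1.37 CPM (SD, n = 2). ALKBH5 (-0.03 ± 0.05), METTL3 (0.05 ± 0.06) and METTL14 (0.01 ± 0.07) did not pass, although ALKBH5 passed with GC and length trends removed uncentred (-0.11). Of 19 TET and DNA methylation genes 5 rose, 2 fell and 12 did not pass, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.786). The methyltransferase gene DNMT3A rose by 0.31 ± 0.07, the endonuclease gene APEX1 by 0.19 ± 0.04 and MBD3 by 0.16 ± 0.05. Of 26 m6A genes 2 rose, 3 fell and 21 did not pass, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.124). Besides FTO, IGF2BP3 rose by 0.18 ± 0.06, and RBM15B fell, with -0.19 ± 0.05. The MBD3 call ended without treated 1, control 1 or control 2 (0.12 to 0.16, adjusted p = 0.0597 to 0.146) and with uncentred GC and length removal or centred GC and length removal (0.01 to 0.08). The RBM15B call ended without treated 2 or control 1 (-0.17 to -0.12, adjusted p = 0.1 to 0.202) and with library totals or the trend removed (-0.15). The IGF2BP3 call ended without treated 2, control 1 or control 2 (0.13 to 0.18, adjusted p = 0.0757 to 0.209).

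Of 24 JmjC histone demethylase genes 0 rose, 2 fell and 22 did not pass, with 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.318). KDM3A (-0.26 ± 0.05) and KDM3B (-0.18 ± 0.05) were the genes that fell. Among 29 collagen hydroxylases and other 2-oxoglutarate enzymes 6 rose, 2 fell and 21 did not pass, with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.124). The lysyl hydroxylase gene PLOD3 rose by 0.33 ± 0.06 and the prolyl 3-hydroxylase gene P3H2 by 0.87 ± 0.19. P4HA1, a subunit of collagen prolyl 4-hydroxylase, had -0.14 ± 0.06 and did not pass, except with GC and length trends removed uncentred (-0.16). HIF is marked for destruction by prolyl hydroxylases. Of 35 HIF targets 4 rose, 6 fell and 25 did not pass, with 5 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.201). NDRG1 (0.54 ± 0.06) and the glucose transporter gene SLC2A3 (1.44 ± 0.19) rose and KDM3A fell, while VEGFA had 0.05 ± 0.07 and did not pass. CA9 had 2 counts in 1 treated library and 0 in the others, and was not tested. Of 20 vitamin C transport and recycling genes 6 rose, 3 fell and 11 did not pass, with 6 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.124, and fry adjusted p = 0.0279). Beside SLC2A3, the dehydroascorbate reductase gene GSTO2 rose (1.35 ± 0.26), and the transporter genes SLC2A1 (-0.26 ± 0.06) and SLC23A2 (-0.16 ± 0.05) fell. Median, mean and test do not share a sign in the HIF, JmjC and TET lists. The KDM3B call ended without control 1 (-0.14, adjusted p = 0.0971) and with library totals or the trend removed (-0.13 to -0.12). The P3H2 call ended without treated 1 (0.68, adjusted p = 0.0873). The SLC23A2 call ended without treated 2, control 1, control 2 or control 3 (-0.17 to -0.14, adjusted p = 0.0690 to 0.136) and with library totals, upper-quartile factors, the 5 CPM filter or the trend removed (-0.14 to -0.11).

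Of 43 DNA replication genes 0 rose, 13 fell and 30 did not pass, with 0 higher and 19 lower adjusted over the list alone. As a list, DNA replication genes had camera adjusted p = 3.38e-07, and adjusted p = 0.275 with an estimated correlation. The single-strand binding protein gene RPA1 had -0.26 ± 0.04, CDC45 had -0.23 ± 0.05 and the polymerase subunit gene POLA1 had -0.22 ± 0.05. Of 36 G2/M genes 0 rose, 7 fell and 29 did not pass, with 2 higher and 10 lower adjusted over the list alone. As a list, G2/M genes had camera adjusted p = 0.000849, and adjusted p = 0.338 with an estimated correlation. MKI67 (-0.18 ± 0.04), CDC20 (-0.18 ± 0.05) and AURKA (-0.17 ± 0.05) were among those that fell. Of 23 tested replication-dependent histone genes 5 rose, 0 fell and 18 did not pass, with 6 higher and 0 lower adjusted over the list alone. As a list, histone genes had camera adjusted p = 0.000530, and adjusted p = 0.218 with an estimated correlation. H2BC5 rose by 0.84 ± 0.15, H2BC11 by 0.79 ± 0.20 and H1-2 by 0.44 ± 0.12. Histone genes are near-identical copies and most of their mRNAs end without a poly(A) tail, so their low counts are uncertain. An added fit that removed the trend with expression ended the G2/M call (adjusted p = 0.332) and took the histone median from 0.75 to 0.41 (adjusted p = 0.0395). Tested against no change with fry, the G2/M list did not pass (adjusted p = 0.0592). The POLA1 call ended without treated 1 (-0.17, adjusted p = 0.0509). The MKI67 call ended without control 2 (-0.16, adjusted p = 0.0612) and with the trend removed (-0.11). The CDC20 call ended without treated 2 or control 1 (-0.16 to -0.12, adjusted p = 0.0606 to 0.129) and with the trend removed (-0.12). The AURKA call ended without treated 2, control 1 or control 2 (-0.17 to -0.14, adjusted p = 0.0543 to 0.0962) and with library totals or the trend removed (-0.13 to -0.12). The H2BC11 call ended without treated 1 or control 1 (0.69 to 0.70, adjusted p = 0.0556 to 0.102) and with the trend removed (0.59). The H1-2 call ended without treated 1 or treated 2 (0.43 to 0.45, adjusted p = 0.0544 to 0.0759) and with the trend removed (0.36).

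Of 39 splicing factor genes 0 rose, 8 fell and 31 did not pass, with 0 higher and 8 lower adjusted over the list alone. As a list, splicing factors had camera adjusted p = 5.39e-05, and adjusted p = 0.218 with an estimated correlation. The spliceosome core gene PRPF8 had -0.19 ± 0.04, PRPF3 had -0.19 ± 0.05 and SF3A1 had -0.18 ± 0.05, and all fell. Of 33 ribosome biogenesis genes 1 rose, 3 fell and 29 did not pass, with 1 higher and 4 lower adjusted over the list alone. As a list, ribosome biogenesis genes had camera adjusted p = 0.00522, and adjusted p = 0.367 with an estimated correlation. NOP16 (-0.18 ± 0.05) and NAT10 (-0.15 ± 0.05) fell and MYBBP1A (0.16 ± 0.05) rose. With the trend over expression removed, the splicing (adjusted p = 0.371) and biogenesis (0.876) calls ended, and the latter also under a filter of 5 CPM (0.0677). Against no change, fry did not call ribosome biogenesis (adjusted p = 0.107). The PRPF8 call ended with the trend removed (-0.10). The PRPF3 call ended without treated 1 or control 1 (-0.17 to -0.16, adjusted p = 0.0624 to 0.0627) and with the trend removed (-0.15). The SF3A1 call ended without treated 2 (-0.12, adjusted p = 0.128) and with the trend removed (-0.11). The NOP16 call ended without treated 1 or control 1 (-0.17 to -0.15, adjusted p = 0.0678 to 0.131) and with library totals or the trend removed (-0.14 to -0.13). The NAT10 call ended without treated 2, control 1 or control 3 (-0.15 to -0.11, adjusted p = 0.0525 to 0.171) and with library totals, upper-quartile factors, the 5 CPM filter or the trend removed (-0.14 to -0.09). The MYBBP1A call ended without treated 1, control 1 or control 2 (0.11 to 0.16, adjusted p = 0.0583 to 0.238) and with DESeq2, uncentred GC and length removal or centred GC and length removal (0.03 to 0.15).

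Ribosomal protein and respiratory chain genes shifted less than 0.1 in median log2 fold change. Of 78 ribosomal protein genes 1 rose, 4 fell and 73 did not pass, with 1 higher and 2 lower adjusted over the list alone. As a list, ribosomal proteins had camera adjusted p = 0.00163, and adjusted p = 0.659 with an estimated correlation. RPL41 (0.18 ± 0.05) rose, and RPL35A (-0.15 ± 0.04) and RPL23 (-0.15 ± 0.04) fell. With the trend over expression removed this list turned upward (adjusted p = 0.0258), and its call ended without control replicate 3 (0.165) or treated replicate 2 (0.737). Of 72 nuclear genes of oxidative phosphorylation 0 rose, 4 fell and 68 did not pass, with 0 higher and 0 lower adjusted over the list alone. As a list, oxidative phosphorylation genes had camera adjusted p = 0.000568, and adjusted p = 0.539 with an estimated correlation. ATP5PB (-0.16 ± 0.04), NDUFB9 (-0.16 ± 0.05) and NDUFA9 (-0.15 ± 0.05) were among the 4 that fell. That call ended with the trend removed (0.364) and without treated replicate 2 (0.0868). Against no change, fry called neither the ribosomal protein list (adjusted p = 0.457) nor this one (0.288). The RPL41 call ended without treated 1, control 2 or control 3 (0.14 to 0.15, adjusted p = 0.0769 to 0.145) and with uncentred GC and length removal (0.12). The RPL35A call ended without treated 2, control 2 or control 3 (-0.15 to -0.13, adjusted p = 0.0702 to 0.0954) and with library totals or the trend removed (-0.11 to -0.08). The RPL23 call ended without treated 2, control 2 or control 3 (-0.14 to -0.12, adjusted p = 0.0832 to 0.112) and with library totals or the trend removed (-0.11 to -0.06). The ATP5PB call ended without control 1 (-0.13, adjusted p = 0.0727) and with the trend removed (-0.09). The NDUFB9 call ended without treated 2, control 1 or control 3 (-0.17 to -0.11, adjusted p = 0.0764 to 0.228) and with library totals, upper-quartile factors, the 5 CPM filter or the trend removed (-0.15 to -0.12). The NDUFA9 call ended without treated 2, control 1, control 2 or control 3 (-0.15 to -0.10, adjusted p = 0.0631 to 0.240) and with library totals, upper-quartile factors, the 5 CPM filter, the trend removed or thinning (-0.14 to -0.11).

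Of 26 unfolded protein response genes 0 rose, 9 fell and 17 did not pass, with 0 higher and 10 lower adjusted over the list alone. As a list, unfolded protein response genes had camera adjusted p = 0.000147, and adjusted p = 0.310 with an estimated correlation. The endoplasmic reticulum chaperone genes HYOU1 (-0.24 ± 0.05), CANX (-0.21 ± 0.04) and CALR (-0.23 ± 0.05) fell. DDIT3, a stress transcription factor gene, had -0.22 ± 0.16 and did not pass. Of 20 heat shock genes 2 rose, 8 fell and 10 did not pass, with 2 higher and 11 lower adjusted over the list alone. As a list, heat shock genes had camera adjusted p = 0.00158, and adjusted p = 0.310 with an estimated correlation. The cochaperone gene STIP1 (-0.28 ± 0.04) and HSPA1B (-0.32 ± 0.05), whose reads can match HSPA1A, fell, while HSPB1 rose by 1.03 ± 0.08. Of 24 cholesterol synthesis genes 0 rose, 8 fell and 16 did not pass, with 1 higher and 11 lower adjusted over the list alone. As a list, cholesterol synthesis genes had camera adjusted p = 0.000163, and adjusted p = 0.294 with an estimated correlation. SQLE (-0.24 ± 0.05) and ACAT2 (-0.23 ± 0.05) fell. Of 20 glycolysis genes 1 rose, 5 fell and 14 did not pass, with 2 higher and 8 lower adjusted over the list alone. As a list, glycolysis genes had camera adjusted p = 0.00216, and adjusted p = 0.367 with an estimated correlation. SLC2A1 had -0.26, PKM -0.20 ± 0.05 and GPI -0.16 ± 0.04. The heat shock (camera adjusted p = 0.107) and glycolysis (0.211) calls ended in the fit with the expression trend removed. The glycolysis call also ended without treated replicate 2. Against no change, fry did not call glycolysis (adjusted p = 0.107). The ACAT2 call ended without control 1 (-0.18, adjusted p = 0.0633). The PKM call ended without treated 2 (-0.15, adjusted p = 0.0518). The GPI call ended without treated 2 or control 1 (-0.15 to -0.12, adjusted p = 0.0619 to 0.122) and with the trend removed (-0.09).

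Of 47 developmental regulators that are Polycomb targets 3 rose, 10 fell and 34 did not pass, with 3 higher and 14 lower adjusted over the list alone. As a list, Polycomb targets had camera adjusted p = 0.00289, and adjusted p = 0.218 with an estimated correlation. GATA6 (-0.38 ± 0.07) and HOXC10 (-0.42 ± 0.08) fell. Of 27 p53 targets 4 rose, 1 fell and 22 did not pass, with 4 higher and 1 lower adjusted over the list alone. As a list, p53 targets had camera adjusted p = 0.0352, and adjusted p = 0.447 with an estimated correlation. TP53I3 rose by 1.11 ± 0.13, the cell cycle inhibitor gene CDKN1A by 0.30 ± 0.06 and PHLDA3 by 0.24 ± 0.07. Of 27 interferon response genes 4 rose, 0 fell and 23 did not pass, with 5 higher and 0 lower adjusted over the list alone. As a list, interferon response genes had camera adjusted p = 0.00388, and adjusted p = 0.310 with an estimated correlation. IFIT5 rose by 0.29 ± 0.07, IFI44L by 0.81 ± 0.22 and STAT2 by 0.23 ± 0.07. The p53 call ended without control replicate 3 (adjusted p = 0.136) or treated replicate 1 (0.179), and the interferon call under a filter of 5 CPM (0.0677). Against no change, fry did not call the p53 list (adjusted p = 0.115). The PHLDA3 call ended without treated 1 or control 2 (0.20, adjusted p = 0.110 to 0.129) and with uncentred GC and length removal (0.13). The IFIT5 call ended without treated 1 (0.25, adjusted p = 0.0664). The IFI44L call ended without treated 2 or control 1 (0.56 to 0.73, adjusted p = 0.0748 to 0.222) and with the trend removed (0.60). The STAT2 call ended without treated 1, treated 2, control 1 or control 3 (0.21 to 0.23, adjusted p = 0.0527 to 0.115).

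The remaining lists did not pass. Of 29 immediate early genes 7 rose, 0 fell and 22 did not pass, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0677). CCN2, the phosphatase gene DUSP1 (0.51 ± 0.07) and ATF3 (0.33 ± 0.07) rose. That list passed without control replicate 1 (adjusted p = 0.0132), control replicate 3 (0.0486) or treated replicate 2 (0.0293), and under a filter of 5 CPM (0.000592). Of 39 ATF4 targets 7 rose, 6 fell and 26 did not pass, with 7 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.728). The mitochondrial enzyme genes PCK2 (0.80 ± 0.09) and ALDH1L2 (0.41 ± 0.06) and the glycine transporter gene SLC6A9 (0.55 ± 0.08) rose, and ASNS had 0.06 ± 0.27 and did not pass. Of 25 citric acid cycle genes 2 rose, 3 fell and 20 did not pass, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.307). OGDH, the 2-oxoglutarate dehydrogenase gene, rose by 0.59 ± 0.05 and IDH2 by 0.28 ± 0.06, and ACO1 fell, with -0.23 ± 0.05. Of 23 serine and one-carbon genes 2 rose, 2 fell and 19 did not pass, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.262, and fry adjusted p = 0.0416). ALDH1L2 rose, and MTHFD1 (-0.21 ± 0.04) fell. Of 15 fatty acid synthesis genes 1 rose, 3 fell and 11 did not pass, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.664). ELOVL6 (0.27 ± 0.06) rose, and ACSL3 (-0.26 ± 0.05) and SCD (-0.16 ± 0.05) fell. The ELOVL6 call ended without treated 2 (0.19, adjusted p = 0.0860). The SCD call ended without control 1 (-0.12, adjusted p = 0.101) and with library totals or the trend removed (-0.12 to -0.09).

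Of 19 imprinted genes 4 rose, 0 fell and 15 did not pass, with 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.218, and fry adjusted p = 0.0279). SGCE rose by 0.41 ± 0.08, CDKN1C by 0.90 ± 0.25, PLAGL1 by 0.18 ± 0.05 and TRAPPC9, named after its value was seen, by 0.24. Of 32 Polycomb and trithorax genes 1 rose, 1 fell and 30 did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.218). PHF19 (0.28 ± 0.07) rose and PCGF6 (-0.18 ± 0.06) fell. Of 30 autophagy and lysosome genes 3 rose, 3 fell and 24 did not pass, with 6 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.728). SQSTM1 (0.20 ± 0.05) and GAA (0.23 ± 0.06) rose and LAMP1 (-0.16 ± 0.05) fell. Of 13 NF-kB targets 1 rose, 0 fell and 12 did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.262), and TNFAIP2 was the gene that rose (0.96 ± 0.23). Of 9 tested germline genes often silenced by DNA methylation 1 rose, 0 fell and 8 did not pass, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.711). TDRD6 was the gene that rose (0.59 ± 0.20). Of 17 nuclear-retained noncoding RNAs, edgeR called 0 (camera adjusted p = 0.786), NORAD having 0.05 ± 0.05 and TUG1 -0.12 ± 0.05. TUG1 passed with DESeq2 (-0.13), without treated replicate 2 (-0.16, adjusted p = 0.0382) and in both added fits with GC and length trends removed (-0.18 uncentred, -0.11 centred). The 13 mitochondrially encoded genes were not analysed here. Median, mean and test differ in sign for the ATF4, fatty acid, germline, lysosome and nuclear-retained lists. The CDKN1C call ended without treated 1 (0.78, adjusted p = 0.139) and with the trend removed (0.68). The PLAGL1 call ended without treated 2 or control 1 (0.11 to 0.17, adjusted p = 0.0872 to 0.239). The PHF19 call ended without treated 1 or control 1 (0.22 to 0.24, adjusted p = 0.0698 to 0.114). The PCGF6 call ended without treated 2, control 1 or control 2 (-0.20 to -0.14, adjusted p = 0.0610 to 0.235) and with library totals, upper-quartile factors, the 5 CPM filter or the trend removed (-0.16 to -0.14). The SQSTM1 call ended without treated 1 (0.14, adjusted p = 0.104) and with uncentred GC and length removal (0.10). The GAA call ended without treated 1 or control 1 (0.19, adjusted p = 0.0922 to 0.101) and with uncentred GC and length removal (0.08). The LAMP1 call ended without treated 2, control 1, control 2 or control 3 (-0.18 to -0.13, adjusted p = 0.0548 to 0.127) and with library totals, upper-quartile factors, the 5 CPM filter or the trend removed (-0.14 to -0.12). The TNFAIP2 call ended without treated 1 (0.83, adjusted p = 0.0853). The TDRD6 call ended without treated 2, control 1 or control 3 (0.37 to 0.57, adjusted p = 0.0655 to 0.405) and with DESeq2, limma-voom, the trend removed or thinning (0.41 to 0.59).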

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

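The cyclic loess, thinned, halved-count and GC and length fits were chosen after seeing the data. No named gene changed direction with a call in any fit, and 36 of 122 named calls were kept in all of them, while 83 were lost against a fold of 1.2 (35 only there) and 50 without at least 1 library. The 2182 calls became 286 against a fold of 1.2 (275 higher, 11 lower), where a larger fold is asked for, 1447 with cyclic loess (519 lower), and 1180 to 2047 with 1 library left out (790 to 1279 higher, 335 to 768 lower). GC and length removal gave 4616 calls (3464 lower) without centring, a version that moves each library's centre by construction, and 3139 with 1466 lower when centred. It was the uncentred version that was run first. Library totals gave 389 lower calls and a filter of 5 CPM gave 542. The cause was not tested for the cyclic loess, centred GC, totals or filter counts. Fewer libraries are tested when 1 is left out. DESeq2 gave 1824 calls (922 higher, 902 lower, 1481 genes with no adjusted p), limma-voom 2183, DESeq2 size factors 2262, upper-quartile factors 2025, no filter 2285, thinning 2018 and halved counts 2238. Of the 20 lists called, 0 passed with an estimated correlation (highest adjusted p = 0.659), 12 kept their direction among 13 called after cyclic loess, where the ribosomal protein list reversed (adjusted p = 0.0258), and 16 to 20 were kept with 1 library left out, among 17 to 21 called. The causes were not tested.

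The groups share replicate numbers 1 and 2, and nothing says that a number marks a shared culture. With the replicate block 1880 genes (1076 higher, 804 lower) and 16 lists were called. The metal response (camera adjusted p = 0.0756), p53 (0.121), ribosomal protein (0.13) and oxidative phosphorylation (0.0544) calls ended there. So did 12 named gene calls: STAT2, SLC7A11, LCP1, RPL35A, NDUFB9, NDUFA9, PCGF6, LAMP1, SLC23A2, TDRD6, KRT17 and SFN. The listings of ended calls in the results leave this fit out. Over 9775 genes, deviations from group means correlated at -0.0605 for the number 1 pair and 0.239 for the number 2 pair. Control 3 and treated 1, which share no number, had 0.254. Deviations of the 2 treated libraries are mirror images, so these correlations are not separate checks. The numbers are therefore not shown to pair the libraries, and pairing is not excluded. The planned mitochondrial share was not run. Of 2402 tested genes under 1 CPM edgeR called 122 higher and 7 lower, and a gene there that did not pass cannot be called unchanged at this depth.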

Other observations

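The tests and genes in this part, apart from the fixed lists and their adjusted p, were chosen after the results were seen. In the HOXB cluster 5 of 9 tested genes fell and in the HOXC cluster 4 of 8, none rising, with HOXB3 at -0.43 ± 0.08, HOXB6 at -0.40 ± 0.06, HOXC8 at -0.41 ± 0.11 and HOXC9 at -0.35 ± 0.07 in log2 fold change ± SE. In the HOXA and HOXD clusters 0 of 19 fell, and HOXA9 (0.33) and HOXD3 (0.48) rose. Among zinc finger genes at the end of chromosome 19, 7 of 55 fell and 0 rose, with a median of -0.14, and among 455 other zinc finger genes 23 fell and 17 rose. ZNF772 (-0.29) and ZNF586 (-0.38) are 2 of the 7.

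Counts for genes with like symbols follow, with no test for enrichment. APOBEC3B, a cytidine deaminase gene, had 35, 26 and 23 counts in the controls and 188 and 182 in the treated libraries, and rose by 2.63 ± 0.21 (edgeR adjusted p = 3.28e-10), while APOBEC3C (0.17), APOBEC3D (1.22) and APOBEC3F (0.52) rose less. Reads can be shared among these paralogs. Annexin genes gave 4 of 11 higher and 0 lower, with ANXA2 at 0.56 ± 0.05 and ANXA3 at 1.11 ± 0.21. Of 20 tested HLA genes 5 rose and 0 fell, the class II genes HLA-DOA (1.07 ± 0.15) and HLA-DRB1 (0.63 ± 0.16) among them. The class II gene HLA-DRA was too low to test, with 6, 6 and 4 counts in the controls and 7 and 14 in the treated libraries. Reads can also be shared among HLA paralogs. Voltage-gated sodium channel genes gave 4 of 11 higher, including SCN2A (0.89 ± 0.15) and SCN2B (1.22 ± 0.17). Of 10 tested genes with symbols starting with CCT and a digit, a set not limited to chaperonin subunits, 5 fell, CCT6A most at -0.22 ± 0.04. Of 9 beta-tubulin genes 3 rose, TUBB2B (0.74 ± 0.07) among them, and TUBB4B fell (-0.14). Of 45 TRIM genes 11 rose and TRIM32 fell (-0.29), and of 22 cytochrome P450 genes 7 rose and CYP4V2 fell (-0.25). ZCCHC12 rose by 0.95 ± 0.06.

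The median log2 fold change was 0.21 in tested genes under 1 CPM and -0.07 in those at or above 200 CPM. Background reads added evenly to all genes would give near-silent genes as much CPM per kb of exon as genes at 1 to 5 CPM, yet they gained 2.62 to 3.55% of it, with classes cut on each control in turn and that control left out of the comparison. A difference in depth is argued against by thinning, after which the median under 1 CPM was 0.20. The slope of the log2 ratio per doubling of CPM was -0.0316 or steeper in every pair of libraries across groups and no steeper than -0.00669 within a group. A compression in library preparation of the treated samples cannot be told apart from a response of the cells, because it would follow the groups, and both stay open.

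Against 10000 random lists matched on expression, 5 of the 20 called lists had medians inside the middle 95%. These were splicing factors (percentile 24.8), G2/M (37.0), ribosome biogenesis (17.1), the unfolded protein response (4.32) and oxidative phosphorylation (4.77). Their medians were thus not shown to stand apart from genes at like levels. With the expression trend removed, the unfolded protein response was still called lower (camera adjusted p = 0.00837), and the other calls among these lists ended. The ribosomal protein median, below 0, lay above its matched lists (99.8). The random lists drew genes independently, so they lack the correlation of a real list and their range may be too narrow. Of the 20 lists not called by camera, 5 lay outside: collagen hydroxylases and other 2-oxoglutarate enzymes (99.98), keratinocyte markers (97.7) and fatty acid synthesis (97.6) above, HIF targets (0.94) and germline genes (1.27) below.

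Of 23 tested histone genes 5 rose and 18 did not pass (list adjusted p = 0.218 with an estimated correlation), and of 43 DNA replication genes 13 fell and 30 did not pass (adjusted p = 0.275 with an estimated correlation). The histone median log2 fold change of 0.75 lay at percentile 100 of the matched lists. It was 0.41 with the trend removed (camera adjusted p = 0.0395 at the preset correlation). This argues against the general rise of low genes as the whole cause only as far as list members vary independently. More cells in S phase would raise DNA replication genes, whose median was -0.12, below the range of matched lists (-0.09 to -0.02), and -0.07 with the trend removed. Weaker poly(A) selection may add reads from RNAs without a tail: those with their own promoters had a log2 ratio of 0.35, but the 6 pairs of libraries ranged from -0.11 to 0.81, and small nucleolar RNAs had 0.01. It therefore stays open, as does an effect of the treatment, which was not tested apart from it.

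Of 34 matrix genes 16 rose, 2 fell and 16 did not pass, and of 11 fibroblast markers 4 rose and 7 did not pass (both lists adjusted p = 0.218 with an estimated correlation). Admixed fibroblasts would bring their abundant transcripts. COL1A2, LUM, DCN, THY1, POSTN and FAP together gained 3.97% of the CPM that COL3A1 gained. Over the 6 pairs of libraries this ran from -1.94 to 9%. These 6 genes were the fibroblast markers too low to test, so a small gain was largely set by their selection. The fibroblast markers called higher, COL3A1, COL1A1, MMP2 and ACTA2, were not in the sum. The comparison therefore cannot decide on admixture. The matrix list median of 0.28 lay at percentile 100 of the matched lists. That argues against a general rise of low genes as the whole cause only as far as list members vary independently. Admixture stays open. An effect of ascorbic acid and other differences in culture or preparation between the groups also stay open and were not tested.

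Splitting the 5 libraries into 2 and 3 in all 10 ways, 1 split, the real one, gave 2182 genes, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes treated and control libraries within a group. A difference between the real groups, whatever its cause, then adds to the spread within groups and lowers the count. The 0 is therefore no measure of how many genes would be called without a difference.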
